A study of Mus musculus with 6 samples.

How the data were processed

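RNA was measured by poly(A)-selected RNA sequencing in 6 samples of mouse lung adenocarcinoma cell lines, 3 of KPCt.SIY and 3 of KPS2.SIY. Per the labels' protocols, cells were collected after 72 hours at 90% confluence. RNA was extracted with TRIzol and cleaned on columns, and 250 ng of it entered an NEB poly(A) library preparation with 14 PCR cycles. Samples were grouped by their titles, and each table column was matched to its sample through the description in the labels.

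The authors deposited 2 tables over the same 56941 Ensembl gene identifiers. The first holds estimated counts per gene, deposited as whole numbers and not scaled between samples. The second holds log2(TPM + 1) values, where TPM is a length-scaled share of transcripts that sums to 1000000, as the values themselves show: undoing the log gave a total of 1000000 in each deposited column. The ratio of a gene's deposited count to its TPM differed between samples by more than 0.1 on the log2 scale, beyond 1 factor per sample, in 13.3% of ratios over 7535 genes with at least 1000 counts. Such ratios arise when effective length is estimated from isoforms, so the counts were treated as estimated counts. The genome build was mm10, per the submitters' processing notes. The aligner, the quantifier, the annotation release and the strand setting are not given in the sources used here.

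Gene symbols, coordinates, lengths and GC content came from the GENCODE M21 annotation of GRCm38. A symbol was found for 51948 identifiers, and 4993 had none. The identifiers without a symbol held between 0.582% and 0.856% of the counts of a sample and were kept in the tests. Coordinates are those of M21, which need not be the release the authors used. Genes that overlap or share sequence with another gene can take its reads in either direction, and the deposited counts do not separate them.

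Total counts ranged from 57570708 to 66188922 per sample. Intervals and lower bounds cover counting error only, since PCR copies cannot be told from separate molecules without molecular identifiers.

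Counts were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr on the groups, TMM scaling factors, and the two-sided quasi-likelihood test (glmQLFit and glmQLFTest) of KPS2.SIY against KPCt.SIY over all 6 samples without covariates. P-values were adjusted over all genes tested by the method of Benjamini and Hochberg, with a threshold of 0.05. Log2 fold changes are KPS2.SIY minus KPCt.SIY and are given with their standard error. Levels are CPM, counts per 1000000 counts after TMM scaling, as mean ± SD over 3 samples. A gene with 0 counts in all samples of a line was given a lower bound of its fold, computed against 3 counts summed over that line's samples and scaled for depth. A gene with 1 to 3 summed counts was given the ratio of summed counts, scaled for depth, with an exact 95% counting interval. Fitted fold changes of such genes depend on the prior count and are not printed.

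Before the data were examined, 45 gene lists with 1234 entries were fixed. They cover immune signals, cell identity, signalling, metabolism, markers of other cell types and RNA quality. Lists with at least 5 tested genes, 43 in number, were tested with camera in limma 3.58.1 at a preset correlation between genes of 0.01. Beside it stand camera with an estimated correlation and fry, whose p asks whether the genes of a list move one way on balance. Each list is also given as counts of members past the threshold over all genes tested and adjusted over the list alone. The lists for MHC class II and for erythroid cells and platelets had 4 tested genes each and were not tested as sets.

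The genes named were set by a rule fixed at the same time. It takes Sox2, Kras, Trp53 and 10 genes tied to the question in the title, whatever their values: Ccl2, Ccl7, Ccl5, Cxcl9, Cxcl10, Tgfb1, Cd274, H2-K1, B2m and Tnfrsf18. It takes the 10 highest and 10 lowest log2 fold changes among genes with an adjusted p under 0.05, a mean of at least 5 CPM in the higher line and no overlap between the samples of both lines. Predicted genes were left out of these 20 and counted: 168 of the 3905 higher genes that met the criteria and 159 of the 3889 lower ones were predicted genes. For each list it takes up to 3 members with the largest change among those past the threshold. Only some of these list members are printed below, and the choice among them was not part of the rule. In some lists the member with the largest change, such as Ptprc of the leukocyte list, is not printed.

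The steps were tested on simulated data, with counts drawn from the real means and library sizes for this comparison and 200 genes changed by known folds. Of 50 genes seeded at each size, edgeR recovered 45 at a log2 change of 0.5, 47 at 1, 50 at 2 and 50 at 3, with 17 false calls among 15529 genes tested. Only genes with a mean of at least 1 CPM were seeded, and genes were drawn independently. In the data 68.9% of tested genes changed, a far larger share. The simulated rates therefore need not hold for genes under 1 CPM or for this comparison.

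Alternatives tried were DESeq2 size factors, upper-quartile factors, library totals, other filters on low counts, the DESeq2 1.42.0 Wald test, limma-voom, limma on the log2 TPM values with 2 pseudocounts, a replicate block, leaving out each sample, centring by GC content and length, and a test against a 1.5-fold change. GC content and length were known for 97.9% of tested genes. Removing each chromosome's median and running camera on ranks were added after the data were seen. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 joined the tables and drew the figures. No sample was left out of the main comparison.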

Results

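KPCt.SIY and KPS2.SIY are cell lines derived from the same mouse lung adenocarcinoma line, which per the labels carries an activated Kras allele and a Trp53 deletion. Both express SIY-GFP, a model T cell antigen fused to a fluorescent protein, and KPS2.SIY also expresses the transcription factor Sox2. The 3 KPCt.SIY samples held 62907818, 57570708 and 65024560 counts, and the 3 KPS2.SIY samples held 62112339, 61932507 and 66188922. Samples of the same line correlated at 0.993 to 0.994 (Pearson's r over genes, on log2 CPM), and their counts differed by more than sampling noise in every pair, with a chi-square per degree of freedom of 4.84 to 12.9. The first principal component separated the lines and held 95.8% of the variance. The labels do not say that the samples of a line came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

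The comparison asks how the transcriptome of these tumor cells differs when Sox2 is expressed, in a study of resistance to checkpoint blockade. Each state of Sox2 is represented by a single cell line. The changes below are therefore differences between the lines, in which Sox2 and any clonal difference are not separated. Sox2 (ENSMUSG00000074637, chromosome 3, 34650405 to 34652461, plus strand) had 0 counts in each KPCt.SIY sample and 33866, 39611 and 40728 counts in the KPS2.SIY samples. Its level in KPS2.SIY was 603 ± 50 CPM (SD, n = 3), at least 37122-fold higher than in KPCt.SIY (adjusted p = 2.12e-11, edgeR). Counts per gene do not tell transcripts of the Sox2 locus from those of an introduced copy. B2m, the shared subunit of MHC class I molecules, fell from 106 ± 3.5 to 51.1 ± 1.9 CPM (log2 fold change -1.05, SE 0.04, adjusted p = 3.36e-09, edgeR). Cd274, which encodes the checkpoint ligand PD-L1, fell from 8.86 ± 0.31 to 6.37 ± 0.36 CPM, and Tgfb1, an immunosuppressive cytokine, fell from 142 ± 9.6 to 105 ± 6.3 CPM. The MHC class I heavy chain gene H2-K1 rose from 167 ± 8.8 to 203 ± 6.6 CPM.

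Kras rose by 0.29 on the log2 scale (SE 0.04), from 78.8 ± 2.2 to 96.5 ± 3.0 CPM. Trp53 transcripts, from a locus the labels describe as deleted, were at 4.87 ± 0.33 and 6.11 ± 0.67 CPM (log2 fold change 0.33, adjusted p = 0.0129, edgeR). That call ended without KPS2.SIY replicate 3 (adjusted p = 0.0551), over all log2 TPM rows (adjusted p = 0.091, limma) and after each chromosome's median was removed (adjusted p = 0.234). The chemokine genes and the receptor gene Tnfrsf18, chosen before the data were examined and named next, were near the floor in both lines. Ccl2, which attracts monocytes, had 3 counts over the KPCt.SIY samples and 37 over the KPS2.SIY samples, a ratio of 12.0 (95% counting interval 3.81 to 61.0, adjusted p = 0.00146, edgeR). Cxcl10, which attracts activated T cells, rose from 0.158 ± 0.082 to 0.353 ± 0.029 CPM (adjusted p = 0.0126, edgeR), and this call ended under DESeq2 (adjusted p = 0.0679). Ccl7 had 0 and 17 summed counts in KPCt.SIY and KPS2.SIY, Ccl5 had 5 and 6, Cxcl9 had 15 and 15, and Tnfrsf18 had 11 and 13. These 4 genes were below the filter and were tested only in the fits without it, where Ccl7 was higher in KPS2.SIY (adjusted p = 0.000356 in edgeR, 0.00675 in DESeq2 and 0.00821 with limma over all log2 TPM rows) and the other genes did not pass (lowest adjusted p = 0.183). Cd274 lies on chromosome 19, whose genes had a median log2 fold change of 0.58. Relative to that chromosome, Cd274 was lower by more, with a log2 fold change of -1.05.

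**Figure D1:**
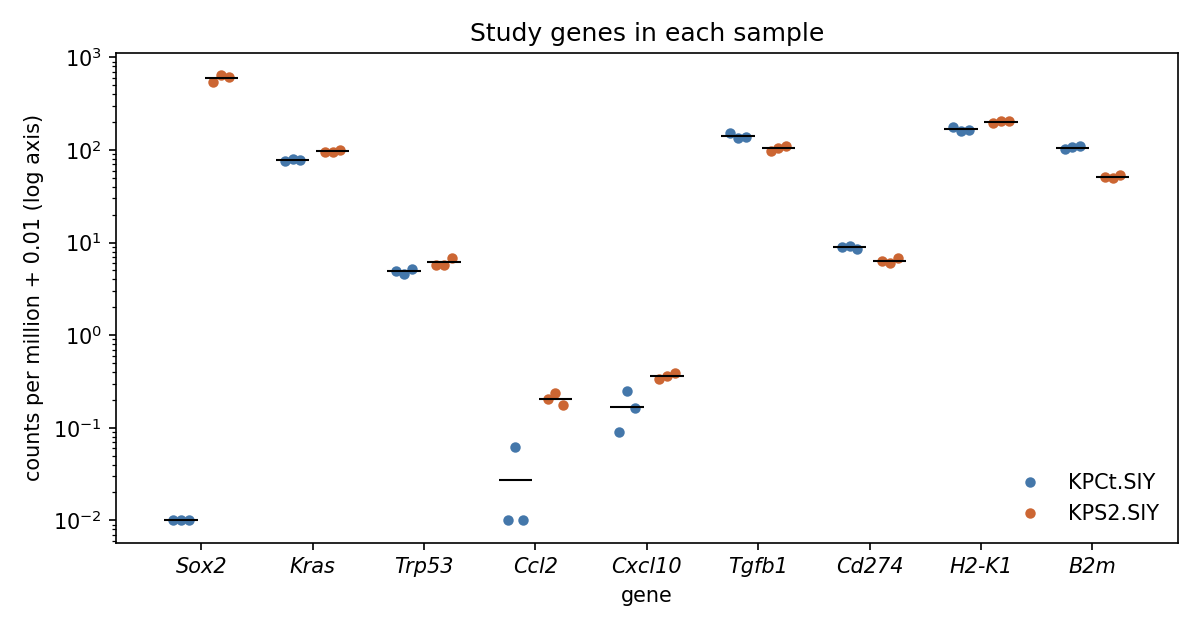
CPM plus 0.01 on a log axis for 9 study genes, with a point per sample (3 KPCt.SIY in blue, 3 KPS2.SIY in orange) and a line at each mean. Sox2 sits at the axis floor in KPCt.SIY, where it had 0 counts, and at 603 CPM on average in KPS2.SIY, while B2m sits lower in all 3 KPS2.SIY samples.

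Of 15757 genes tested, 10854 (68.9%) changed, 5390 higher and 5464 lower in KPS2.SIY. A change of at least 2-fold was seen in 2572, of which 1179 were higher and 1393 lower. The member counts of the lists below are to be read beside this 68.9%, and beside the 49.7% of changed genes that were higher. A list called at about that rate does not stand out by its number of calls. Several genes were expressed in only 1 of the lines. Pgrmc1, which encodes a heme-binding membrane protein, had 0 counts in KPCt.SIY and 65.9 ± 2.0 CPM in KPS2.SIY, at least 4054-fold higher. Cacna2d1, a calcium channel subunit gene, was at least 1104-fold higher, the phosphodiesterase gene Pde3b at least 615-fold, the scaffold gene Homer2 at least 430-fold and Map9, which encodes a microtubule-associated protein, at least 347-fold. Arrdc4 had 1 count against 4280, a ratio of 4174 (95% counting interval 749 to 164885). Ppp2r2b, Slc24a3 and Krba1 complete the 10 highest, with ratios of 1365, 978 and 513.

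In the other direction, Nid2, a basement membrane gene, fell from 34.5 ± 0.86 CPM to 1 count over the 3 KPS2.SIY samples, a ratio of 6592 (95% counting interval 1183 to 260407). Cdh2, which encodes N-cadherin, fell from 55.1 ± 0.53 to 0.0426 ± 0.034 CPM (log2 fold change -10.28, SE 0.12, adjusted p = 1.86e-12, edgeR). Rasef was at least 768-fold lower, Dapk1, a death-associated kinase gene, at least 528-fold and Bmyc, a Myc paralog, at least 404-fold. Zfp422, Sema6a, Ephb2, Zfp612 and Slco3a1 complete the 10 lowest, with ratios of 4639, 1336, 1204, 1162 and 973. Bmyc shares 60.9% of its 50-base words with another gene, so its count is less certain than the rest.

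Of 14 tested chemokine genes 8 fell and 3 rose. Cxcl3, a neutrophil attractant, fell from 5.51 ± 0.46 to 0.433 ± 0.010 CPM, and Ccl20 fell from 2.57 ± 0.65 to 0.344 ± 0.048 CPM. The list passed camera (adjusted p = 0.0193), with an adjusted p = 0.746 with an estimated correlation. Of 24 targets of NF-kB, 13 fell and 4 rose (adjusted over the list alone, 14 and 4). The adhesion gene Vcam1 fell from 316 ± 62 to 25.3 ± 2.4 CPM, the complement gene C3 from 15.6 ± 4.2 to 0.148 ± 0.013 and the lipocalin gene Lcn2 from 1.35 ± 0.27 to 0.0267 ± 0.019. NF-kB targets passed camera (adjusted p = 0.00238), with an adjusted p = 0.746 with an estimated correlation. Complement and coagulation genes followed, with 14 of 24 lower and 5 higher, among them C1s1 (log2 fold change -5.11) and Cfi (-4.33). That list passed camera (adjusted p = 7.17e-05), with an adjusted p = 0.746 with an estimated correlation.

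Other immune lists did not pass camera. Of 26 cytokine genes 15 fell and 6 rose (adjusted over the list alone, 16 and 6, camera adjusted p = 0.324). Tgfb2 and Tnf fell, from 3.24 ± 0.21 to 0.186 ± 0.064 CPM and from 1.96 ± 0.36 to 0.166 ± 0.12 CPM, while Ido1, a tryptophan-degrading enzyme, rose from 0.0474 ± 0.040 to 1.48 ± 0.096 CPM. Among 16 genes of checkpoint ligands and costimulation, which include ligands of natural killer cell receptors, 9 fell and 1 rose (adjusted p = 0.332), and Vtcn1 and Ulbp1 had log2 fold changes of -2.09 and -1.12. That of Ulbp1 was -0.66 with chromosome medians removed, and its call ended over all log2 TPM rows (adjusted p = 0.103, limma). Of 18 MHC class I genes 8 fell and 6 rose (adjusted p = 0.719). Nlrc5, a transactivator of MHC class I, was near the floor in both lines, with 53 summed counts in KPCt.SIY and 8 in KPS2.SIY (log2 fold change -2.69). The peptide transporter gene Tap2 rose from 1.26 ± 0.22 to 3.82 ± 0.050 CPM. Type I interferon response genes were 13 lower and 6 higher of 28 (adjusted p = 0.372): Epsti1 fell by 5.70 on the log2 scale and Mx1 rose by 5.00. Interferon gamma GTPases and regulators were 7 higher and 6 lower of 15, with Gbp9 at 3.19. Their median of 0.31 and mean of 0.71 were positive while camera's direction was down (adjusted p = 0.501). RNA sensing and STING genes were 11 lower and 4 higher of 18 (adjusted p = 0.344), including Tlr3 at -1.45. In these immune lists, apart from the cytokine genes and NF-kB targets, the counts adjusted over the list alone were the same.

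Cell identity genes moved in both directions. Muc5ac, a gel-forming airway mucin, rose from 8.84 ± 1.1 to 965 ± 110 CPM (log2 fold change 6.77, SE 0.11, adjusted p = 7.7e-12, edgeR). Muc5b rose from 2.86 ± 0.16 to 17.7 ± 2.4 CPM and Foxj1, a regulator of ciliated cells, fell from 2.23 ± 0.20 to 0.280 ± 0.018 CPM. The airway list had 4 higher and 3 lower of 11 members and passed camera (adjusted p = 0.0137), with an adjusted p = 0.746 with an estimated correlation. Alveolar type 2 genes were 7 lower and 2 higher of 11 (adjusted p = 0.174), including Lyz2 (-5.24) and Muc1, which fell from 342 ± 28 to 110 ± 2.2 CPM. Among 13 alveolar type 1 genes 6 rose and 4 fell (5 adjusted over the list alone, adjusted p = 0.812): the tight junction gene Cldn18 fell from 169 ± 3.8 to 0.310 ± 0.078 CPM and the water channel gene Aqp5 rose from 7.50 ± 0.86 to 233 ± 13 CPM. The camera direction of this list was up, against a median and a mean of -0.04.

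Squamous and basal genes were 10 higher and 5 lower of 18 (adjusted p = 0.332), with Krt13 at 4.01 and Krt6a, which had 0 counts in KPCt.SIY, at least 25.4-fold higher. Gastric and gut genes were 11 higher and 9 lower of 21 (adjusted p = 0.376), with Hnf1a at 4.01 and Gata4 at -3.26. Epithelial adhesion and keratin genes were 9 higher and 10 lower of 24 (adjusted p = 0.501), with Spint1 at 4.60 and Ehf at -5.08, and their median of -0.04 differed in sign from their mean of 0.39. Mesenchymal genes were 7 higher and 10 lower of 22 (adjusted p = 0.436), with Cdh2 at -10.28 and the matrix gene Tnc at 4.33. Collagen and matrix genes were 17 lower and 7 higher of 31, and the list passed camera (adjusted p = 0.00157), with an adjusted p = 0.721 with an estimated correlation. Besides Nid2, Loxl1 was at least 63.6-fold lower, while Tgfbi rose by 4.75 on the log2 scale. Neural genes were 6 higher and 6 lower of 14. They passed camera downward (adjusted p = 0.00162), with an adjusted p = 0.721 with an estimated correlation and 0.789 with camera on ranks. Their median was -0.45 but their mean was -0.02, with 6 members at least 2-fold higher and 4 at least 2-fold lower. The downward direction is therefore weakly based. Cdh2 was the lowest member, while Sox21 and the neuronal gene Map2 rose by 4.94 and 4.58 on the log2 scale. Apart from Sox2 itself, which no list holds, 4 of 6 SOX family genes rose and 1 fell (adjusted p = 0.372), with Sox6 at 3.07 and Sox7 at -6.74. The call of Sox6, which was at 0.033 and 0.286 CPM, ended on log2(TPM + 1) (adjusted p = 0.156, limma). Pluripotency genes were 3 higher and 3 lower of 6 (adjusted p = 0.719), with the RNA-binding protein gene Lin28b at 6.31. Their median of -0.12 and mean of 0.52 differed in sign. In the identity lists other than that of alveolar type 1 genes, the counts adjusted over the list alone were the same.

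Cell cycle genes were higher in KPS2.SIY. Of 38 S phase genes 29 rose and 3 fell, including the replication licensing gene Cdc6, from 0.871 ± 0.16 to 3.30 ± 0.12 CPM. Of 36 genes of G2 and M phase 30 rose and 3 fell, including the mitotic kinase gene Aurkb, from 1.05 ± 0.34 to 4.87 ± 0.48 CPM, and Ube2c (log2 fold change 1.76). They passed camera (adjusted p = 0.0179 and 0.00857), with adjusted p = 0.75 and 0.807 with an estimated correlation. Hypoxia and glycolysis genes were 23 higher and 9 lower of 36 (adjusted over the list alone, 23 and 10), with the lactate transporter gene Slc16a3 at 2.08 and Car12 at -2.60. That list passed camera (adjusted p = 0.0102), with an adjusted p = 0.746 with an estimated correlation. Cholesterol synthesis genes were 16 lower and 1 higher of 25 (adjusted over the list alone, 19 and 1), including Pcsk9 at -4.24 and Sqle at -0.75. They passed camera (adjusted p = 0.0137), with an adjusted p = 0.807 with an estimated correlation. Immediate early genes were 15 lower and 4 higher of 22: Atf3 fell from 123 ± 5.9 to 13.2 ± 0.66 CPM and Nr4a1 from 111 ± 21 to 37.6 ± 3.1 CPM. They passed camera (adjusted p = 0.0102), with an adjusted p = 0.746 with an estimated correlation.

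**Figure D2:**
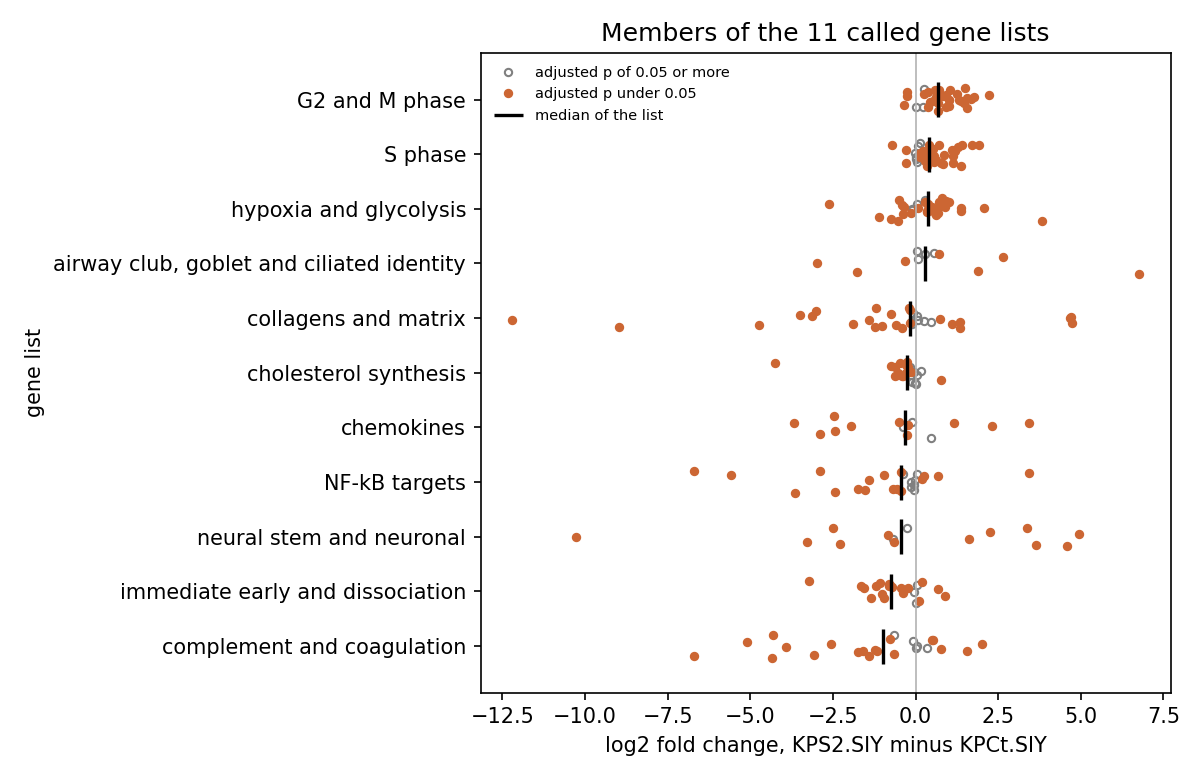
Log2 fold change (KPS2.SIY minus KPCt.SIY) of each tested member of the 11 lists that passed camera, with filled points for an adjusted p under 0.05, open points for the rest and a bar at each list's median. Members of the 2 cell cycle lists lie mostly right of 0, and those of the complement list, with a median of -0.97, mostly left. The fitted positions of Nid2, Loxl1 and Ccl2 depend on the prior count.

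Shares of counts used here as measures of RNA quality differed between the lines, while none of the RNA quality lists passed camera. A difference in RNA quality cannot be told from a difference between the cells. Mitochondrial transcripts held 2.75% to 2.89% of the counts in KPCt.SIY and 2.16% to 2.42% in KPS2.SIY. The 10 most abundant genes held 8.46% to 8.97% and 7.08% to 7.26%. Of 15 mitochondrial genes 8 fell and 3 rose (camera adjusted p = 0.436), with the largest change in mt-Rnr1, a ribosomal RNA gene that rose from 159 ± 12 to 285 ± 18 CPM, and mt-Nd5 at -0.76. Of 45 cytosolic ribosomal protein genes 16 rose and 10 fell (camera adjusted p = 0.538), led by Rpl6 at 0.52. With chromosome medians removed, 24 rose and 4 fell (camera adjusted p = 0.267), and Rpl6 was at 0.33. Replication-dependent histone genes were 7 lower and 0 higher of 11 (camera adjusted p = 0.372), beside the rise of the S phase genes. Among them Hist1h4d was at -1.91 but near the floor, with 38 summed counts in KPCt.SIY and 10 in KPS2.SIY. In these RNA quality lists and in the cell cycle and immediate early lists, the counts adjusted over the list alone were the same.

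Tests of single genes used edgeR with Benjamini-Hochberg adjustment unless DESeq2 or limma is named, and 11 of 43 lists passed camera. With an estimated correlation 0 lists passed, 2 had an unadjusted p under 0.05, and fry passed 36. Calls of the chemokine, airway, collagen and neural lists also ended under limma-voom, with adjusted p of 0.175, 0.321, 0.0927 and 0.692, and on log2(TPM + 1), where that of the immediate early list ended too (adjusted p = 0.0775, and 0.0941 on log2(TPM + 0.1)). With camera on ranks the chemokine, airway, collagen and neural calls ended as well, with adjusted p of 0.18, 0.351, 0.119 and 0.789.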

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

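Removing chromosome medians and running camera on ranks were chosen after the data were seen, and the other settings before. Across the scaling factors, filters, tests, GC and length centring and log2 TPM values tried, the number of changed genes ran from 9527 to 11595 against 10854. Testing against a 1.5-fold change left 3168, since it asks for a larger effect. The number changed at least 2-fold was 1605 with at least 1 CPM in 3 samples, where fewer genes were tested. It was 1054 on log2(TPM + 1) both as deposited and rebuilt, and 1060 over all log2 TPM rows, against 2572, since the pseudocount shrinks the fold of low genes. Without each sample in turn, 10259 to 10757 genes changed, 2675 to 2718 of them at least 2-fold, and 11 to 13 lists passed. Sox2 stayed higher in KPS2.SIY in every fit.

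The number of lists was less stable: 11 passed camera, against 7 with limma-voom, 6 on log2(TPM + 1) as deposited, 6 on log2(TPM + 1) rebuilt, 6 on log2(TPM + 0.1), 7 with camera on ranks, 0 with an estimated correlation and 36 with fry. Camera's preset correlation was 0.01, while the estimated correlation had a median of 0.118 over the lists. In the lists that passed it ran from 0.021 (collagens and matrix) to 0.63 (cholesterol synthesis). Its share in the fall to 0 and the causes of the other differences between these settings were not tested, though fry asks another question. The S phase, G2 and M phase, hypoxia, cholesterol, NF-kB and complement lists passed in each of these settings except with an estimated correlation. Some lists that did not pass camera passed in settings other than fry. The MAPK list did so without the filter on low counts (adjusted p = 0.00865), over all log2 TPM rows (0.0288), with the replicate block (0.0361), with the block and GC and length centring (0.0474) and without KPS2.SIY replicate 1 (0.0299) or 2 (0.0467). The YAP and TAZ list did so without the filter (0.00615), over all log2 TPM rows (0.024), with GC and length centring (0.031), with the block (0.0238), with both (0.0167) and without KPCt.SIY replicate 2 (0.0172) or KPS2.SIY replicate 2 (0.0439). The histone and RNA sensing lists passed over all log2 TPM rows (0.035 and 0.0217).

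Equal replicate numbers did not pair the samples: their deviations from the line means correlated at -0.26, -0.27 and -0.02, and no sample correlated best with its own number. With the replicate block 10204 genes changed, 2565 of them at least 2-fold, and 13 lists passed. Removing chromosome medians left 10063 changed genes, which kept 8393 of the calls (77.3%), and 11 lists.

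The direction given by camera turned in 6 lists that passed neither before nor after, so it is not settled for them. The retinoid list turned up without the filter on low counts (adjusted p = 0.933), with limma-voom (0.483), on log2(TPM + 1) as deposited and rebuilt (0.576 each), on log2(TPM + 0.1) (0.59), over all log2 TPM rows (0.343), on ranks (0.425) and without KPS2.SIY replicate 1 (0.903), 2 (0.905) or 3 (0.762). The stress response list turned up with limma-voom (0.721), on log2(TPM + 1) as deposited and rebuilt (0.793 each), on log2(TPM + 0.1) (0.798), over all log2 TPM rows (0.876) and on ranks (0.698). Endothelial genes turned up without the filter (0.855) and over all log2 TPM rows (0.792). Epithelial genes turned down over all log2 TPM rows (0.906). With chromosome medians removed, fatty acid genes turned down (0.205) and oxidative phosphorylation genes up (0.92). The cause was not tested. No named gene and no list past the threshold turned in the settings run.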

Other observations

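The test of shared sequence, the matched comparison genes beside the paralog test, and the test of depth were chosen after related values were seen; the other tests below were set out beforehand. Signalling genes moved in both directions, and none of their lists passed camera. MAPK output genes were 16 higher and 5 lower of 25 (adjusted p = 0.0662), with the phosphatase gene Dusp5 rising from 58.1 ± 4.0 to 236 ± 16 CPM and Spry1 falling from 28.4 ± 2.3 to 7.16 ± 0.20. YAP and TAZ targets were 13 lower and 6 higher of 23 (adjusted p = 0.059), including Fjx1, from 72.8 ± 4.5 to 8.49 ± 0.59 CPM. WNT genes were 10 higher and 9 lower of 24 (10 and 10 adjusted over the list alone, adjusted p = 0.752), with Wnt4 at -3.06 and Dkk2 at 2.22. NOTCH genes were 8 lower and 5 higher of 14 (adjusted p = 0.162), with the ligand gene Dll1 at -3.66 and the target Hey1 at 2.69. BMP and TGF-beta targets were 12 higher and 12 lower of 26 (adjusted p = 0.372), with Fst at 3.91 and Smad9 at -4.37, and their median of 0.04 and mean of -0.17 differed in sign. Targets of p53, whose gene these lines lack per the labels, were 11 lower and 5 higher of 27 (11 and 4 adjusted over the list alone, adjusted p = 0.372), with Gdf15 at -1.45, while Eda2r rose from 1 to 55 and Fas fell from 74 to 2 summed counts.

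The metabolic lists described here did not pass camera either. NRF2 and glutathione genes were 14 higher and 12 lower of 29 (adjusted p = 0.87), with Aldh3a1 at 1.93 and Cbr1 at -2.48. Retinoid genes were 11 higher and 6 lower of 18 (adjusted p = 0.87), with Aldh1a3 rising from 25.2 ± 1.3 to 150 ± 12 CPM and Rarb at -6.18, and their median of 0.24 and mean of -0.16 differed in sign. Fatty acid genes were 11 higher and 6 lower of 21 (camera adjusted p = 0.798), with Elovl5 at -1.12, and their median of 0.18 and mean of -0.01 differed in sign. With chromosome medians removed, 4 fatty acid genes were higher and 10 lower. Oxidative phosphorylation genes were 21 lower and 12 higher of 42 (camera adjusted p = 0.812), with Ndufb8 at 0.79 and Ndufa1 at -0.64. With chromosome medians removed, 15 of them were lower and 14 higher, and Ndufb8 and Ndufa1 were at 0.22 and -0.42. MYC targets were 18 higher and 9 lower of 33 (camera adjusted p = 0.372), with Tfrc falling from 72.8 ± 6.7 to 36.5 ± 2.7 CPM. Stress response genes were 14 higher and 10 lower of 31 (15 and 10 adjusted over the list alone, adjusted p = 0.736), with Aldh1l2 at -1.78, and their median of 0.09 and mean of -0.09 differed in sign. Markers of other cell types moved apart: among 6 leukocyte and macrophage genes, Mrc1 rose from 6.34 ± 1.2 to 66.8 ± 4.2 CPM and Lcp1 fell from 13.0 ± 1.2 to 0.265 ± 0.068, with 2 higher and 4 lower (adjusted p = 0.146). Endothelial genes were 5 higher and 4 lower of 10 (adjusted p = 0.87), with Kdr at -3.68, and fibroblast genes were 3 lower and 0 higher of 5 (adjusted p = 0.436), with Pdgfra at -3.51. Of the lists too small to test, Cd74 of MHC class II was at -1.94 and Epor of the erythroid genes at 0.99. Both were low: Cd74 fell from 130 to 34 summed counts and Epor rose from 181 to 366.

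Leaving out Sox2, 56 genes were on at 1 CPM or more in a line and had at most 3 summed counts in the other, 20 off in KPCt.SIY and 36 off in KPS2.SIY. Low depth cannot account for them, since an unchanged level would have given a median of at least 639 counts, and a lost chromosome block would leave neighbours off together, which held for 4 genes (7.1%, exact 95% interval 2.0% to 17.3%; Mageh1 with Rragb on X, Cyp2j9 with Cyp2j5 on 4, all named after their values were seen), although more than in most of 10000 shuffles (p = 0.0065). For 57.1% (exact interval 43.2% to 70.3%) an overlapping or same-stem gene gained as much as 50% of the loss, which passed the 25% set beforehand for reads moved to a paralog; that threshold was too low, because 46.5% of 1120 other genes of matched level passed it too. The test added then found that 1 gene, or 1.8% (exact interval 0% to 9.6%), shared 50% or more of its 50-base words with another gene of the annotation, so moved reads are a poor explanation for the set, though this rests on a criterion changed after the first result. Silencing or loss of single genes in the cells each line grew from may explain the pattern; Sox2 and any clonal difference between the lines are not separated by this design.

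Genes of whole chromosomes shifted together. Over genes with at least 5 CPM, the median log2 fold change was 0.58 on chromosome 19 (bootstrap 95% interval 0.55 to 0.62), 0.32 on 12, 0.31 on 2, -0.25 on 3 and 9, -0.26 on X and -0.46 on 10. These 7 chromosomes lay beyond 0.2 in size and outside all of 10000 random gene sets. In all, 12 of 20 chromosome medians lay outside the random sets, among them those of 5 and 11 at 0.2. The median of chromosome 19 was 0.58 to 0.59 in each KPS2.SIY sample. GC content and gene length do not account for it, since centring by both kept 101.4% of the median of chromosome 19. A copy number difference between the lines is a candidate explanation, but DNA was not measured and regional regulation was not tested. A ratio of 3 copies to 2 would give 0.58, which the median of chromosome 19 matches and the other medians do not. Other ratios of copies were not tried, so the other medians do not speak against a copy number difference.

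Of 11 replication-dependent histone genes 7 fell and 0 rose (median -1.02), but the list did not pass camera (adjusted p = 0.372, and 0.746 with an estimated correlation), while 29 of 38 S phase genes rose and 3 fell (adjusted p = 0.0179, and 0.75 with an estimated correlation). The histone median was -1.06 after centring by GC content and length, which argues against those as the cause. Weaker carry-over of RNA without a poly(A) tail may contribute, but it cannot be told apart: the other such transcripts had a median of 0.03 over 5 tested genes, of which 2 reached 1 CPM. No biological explanation was tested.

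Splits of the 6 samples into 3 and 3 number 10, too few for a share under 0.05. The lines gave 10854 changed genes and 2572 changed at least 2-fold, while the highest of the other splits gave 0 in edgeR for both. So 1 of the 10 splits gave as many. The other splits had 43 to 146 genes at an unadjusted p under 0.05 in edgeR. Each of them mixes both lines within its groups, so the difference between the lines widens the spread within groups. Their 0 was therefore to be expected and cannot decide the question. For gene lists the lines gave 11 and the highest other split 12, so 2 of the 10 splits gave as many. That split set KPCt.SIY replicate 1 with KPS2.SIY replicates 1 and 2 against the rest. The groups of the other splits hold the lines in unequal numbers, so part of the line difference remains between them. Their 2 to 12 lists therefore cannot decide the question either.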
